A study of Mus musculus with 2 samples.

How the data were processed

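Transcript levels were measured by RNA sequencing in mouse samples labelled as adipose, of 2 genotypes, wild type (WT) and Trappc9 knockout (KO), with 1 library each. Trappc9 encodes a subunit of the TRAPP complexes, which act in vesicle transport between endomembranes. Per the series' design text, fat pads from the abdomen of 3 WT and 3 KO mice aged 3 to 4 weeks were digested with collagenase, strained and pelleted, and the pellet went into TRIzol. The libraries' titles call the material stem cells of adipose tissue, whereas the extraction label speaks of frozen pads; which of these preparations was sequenced, and whether the mice were pooled into the 1 library per genotype, is not given in the sources used here. Libraries were made with the Illumina TruSeq RNA kit from 1 µg of total RNA, per the labels' protocols.

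The deposited table gives 1 FPKM value per gene and library (fragments per kilobase of gene length, divided by a library size), with the gene length, position and biotype, for 54532 genes. The submitters' processing notes name HISAT2 2.0.5 and the builds mm10 and hg38; the program that counted fragments is not given in the sources used here. All coordinates are those of the table. Of its gene identifiers, 54495 occurred in GENCODE M21 (GRCm38, the assembly also called mm10), and 53585 of these had the same chromosome, start and end there. For gene lists and named genes, the line with the higher mean was used where a symbol stood on more than 1 line of the table (105 repeats). Counts over all genes and the pool for random lists kept every line.

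Because the gene length is in the table, the fragments behind each FPKM value could be recovered. FPKM multiplied by length was a whole multiple of 1 step per library for 100% of the values above 0, within 0.01 of a fragment. This gave 13705193 fragments for the library labelled WT and 14783728 for the library labelled KO. The denominators behind the deposited FPKM values were not these totals: their KO over WT ratio was 1.01, against 1.08 for the totals. Divided by their geometric mean they were 0.995 and 1.005, the same as the median-of-ratios size factors computed from the recovered fragments. The deposited FPKM values therefore already carry a scaling between libraries that compensates for differences in composition, and no further scaling was applied to them. A single fragment on a gene of 1 kb was worth 0.0706 FPKM in the library labelled WT and 0.0699 FPKM in the library labelled KO.

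With 1 library per genotype there is no replicate check and no p-value was computed. Differences are given as log2((KO + 1)/(WT + 1)), with a pseudocount of 1 FPKM, which understates the change of genes at low levels. A protein-coding gene with a mean of at least 1 FPKM was counted as higher or lower when this log2 ratio reached 1 in either direction (2-fold). Each ratio has an exact 95% Clopper-Pearson interval from the recovered fragments, taken on the share of a gene's fragments that came from the library labelled KO. These intervals cover counting error only, not the spread between animals or preparations, and the reads carried no molecular identifiers in the sources used here. A gene is said to be higher or lower beyond counting error when this interval excluded no change.

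Genes were picked for naming by fixed rules, and not all of those picked are named below. Trappc9 came first. Next were the 12 with the highest and the 12 with the lowest log2 ratio among protein-coding genes with a mean of at least 5 FPKM. Up to 4 members of each gene list with the largest ratios in either direction followed, with a fixed set of adipose, dopamine receptor, immune and TRAPP-related genes. Other genes were named after their values were seen, which is said where it applies. Before the data were examined, 46 gene lists were fixed, covering TRAPP and Trappc9 biology, dopamine and adrenergic signalling, inflammation, fat metabolism, proliferation, stress, matrix, organelles, developmental pathways, sex-linked genes and markers of cell types that a fat pad or its neighbours could hold. The median log2 ratio over a list's measured members (mean of at least 1 FPKM) was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A list was called above or below when it fell outside the middle 95% of these, which describes the pair of libraries and not the genotypes. Of the lists, 44 had the required 3 measured members. If members varied independently, 2.2 of these lists would fall outside by chance. Where members vary together or lists share genes, more can fall outside, so this number does not exclude chance. A further 8 lists of epididymal, epithelial, germ cell, testicular somatic, fibroblast and matrix genes were written after the values were seen. They appear in the closing section and, for spermatocytes, once in the results, where the epididymal and germ cell lists also define a count without them. Of these 8 lists, 1 was assembled from genes already seen to be high, and the members of the others were chosen without looking at their values.

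The procedure was tested on simulated data with the real genes and depths, over 13084 genes. Between unchanged libraries, counting alone put 2 genes at least 2-fold higher and 1 lower, and 4.30% of genes fell beyond their counting interval. The genes given a change were drawn only from those with a mean of at least 5 FPKM. All their simulated changes of 2.5-fold and 4-fold passed the 2-fold rule (100% of each), with 5 unchanged genes passing it. Changes of genes with a mean of 1 to 5 FPKM, on which the pseudocount weighs more, were not simulated, so the share passing there is not known. A list raised 1.3-fold stood at percentile 100. In the unchanged pair, 2 of 43 lists fell outside the middle 95%, with counts drawn independently for each gene.

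Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5 FPKM, no filter or a mean of at least 5 FPKM, 4 other scalings, thresholds of 1.5-fold and 4-fold, all biotypes, unmatched random lists, list means, lists without their farthest member, the counts without marker genes and the counts with the counting interval as an added condition. Scaling by each library's own fragment total was added after the data were seen. So were the counts without the listed epididymal and germ cell genes and genes with Defb, Spink, Lcn, Cst or Rnase symbols. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.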

Results

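RNA was sequenced from samples labelled as abdominal adipose tissue of young mice, aged 3 to 4 weeks, of 2 genotypes: WT and a knockout of Trappc9, a TRAPP complex subunit. Each genotype was represented by 1 library, so no difference below has a replicate check. The recovered depth was 13705193 fragments in the library labelled WT and 14783728 in the library labelled KO, of which 97.7% and 97.8% fell on protein-coding genes. Mitochondrially encoded genes took 1.46% and 1.89% of the fragments, and the 10 genes with the most fragments took 6.17% and 6.94%. In all, 27725 and 27247 of 54532 genes were above 0. Values are given as deposited FPKM, in the library labelled WT first, and differences on the log2(FPKM + 1) scale.

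The first question was whether the targeted gene was reduced. Trappc9 (ENSMUSG00000047921, chromosome 15, 72589620 to 73061204, mm10) stood at 9.94 FPKM in the library labelled WT, from 1117 fragments, and at 12.6 FPKM in the library labelled KO, from 1432 fragments. The ratio of FPKM was 1.27, with a 95% counting interval of 1.17 to 1.37, so the gene-level value was not lower in the library labelled KO. The value covers the whole gene and was not split by exon, so it cannot show a deletion or a premature stop that leaves most of the transcript in place. As the gene-level value neither bears out nor contradicts the label, the libraries are named by their labels throughout. Every direction below is from the library labelled WT to the library labelled KO.

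Genes of the TRAPP pathway differed by small amounts. The 14 measured subunits, Trappc9 itself included, had a median log2 ratio of 0.13. This was within the matched random lists although near their upper end (percentile 97.4). Beyond counting error, 6 were higher, among them Trappc9, Trappc6a (18.9 and 25.3 FPKM) and Trappc4 (11.3 and 13.9 FPKM), and 0 were lower. Of all 13084 measured protein-coding genes, 3220 were higher and 2297 lower beyond counting error. Trappc10, specific to the TRAPPII complex together with Trappc9, was at 13.4 and 14.8 FPKM, and Trappc13 at 8.91 and 8.09 FPKM. Rab GTPases linked to TRAPP, which direct vesicle traffic, had a median of 0.11, within the random lists, with Rab18 at 42.5 and 46.0 FPKM and Rab11a at 22.7 and 25.9 FPKM. Genes of the imprinted region around Trappc9, again with Trappc9 included, had a median of 0.13, also within. Peg13, a noncoding RNA transcribed from within Trappc9, was at 7.46 and 8.60 FPKM. After rescaling to TPM, in which both libraries have the same sum, the medians of these 3 lists were below 0 (−0.05 for the TRAPP subunits).

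Across 13084 protein-coding genes with a mean of at least 1 FPKM, 124 were at least 2-fold higher in the library labelled KO and 38 at least 2-fold lower, together 1.24% of the genes. For 122 and 34 of these the counting interval excluded no change. Over all 13084 genes, 3220 were higher and 2297 lower beyond counting error, the background for such counts among list members. The middle 90% of log2 ratios ran from −0.41 to 0.44 around a median of 0.02, and the levels correlated across genes with r = 0.981, where genes are not independent replicates. The counts depended on the scaling, whereas relative to the median of all genes the higher ones stayed more numerous under every scaling tried. After rescaling to TPM, which moved the median of all genes by −0.19, the split was 177 higher and 277 lower, or 239 and 145 relative to that median. After rescaling without the most abundant genes, a move of −0.11, the split was 253 and 297, or 296 and 218 relative to the median. With a pseudocount of 5 FPKM the counts were 66 and 2.

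**Figure D1:**
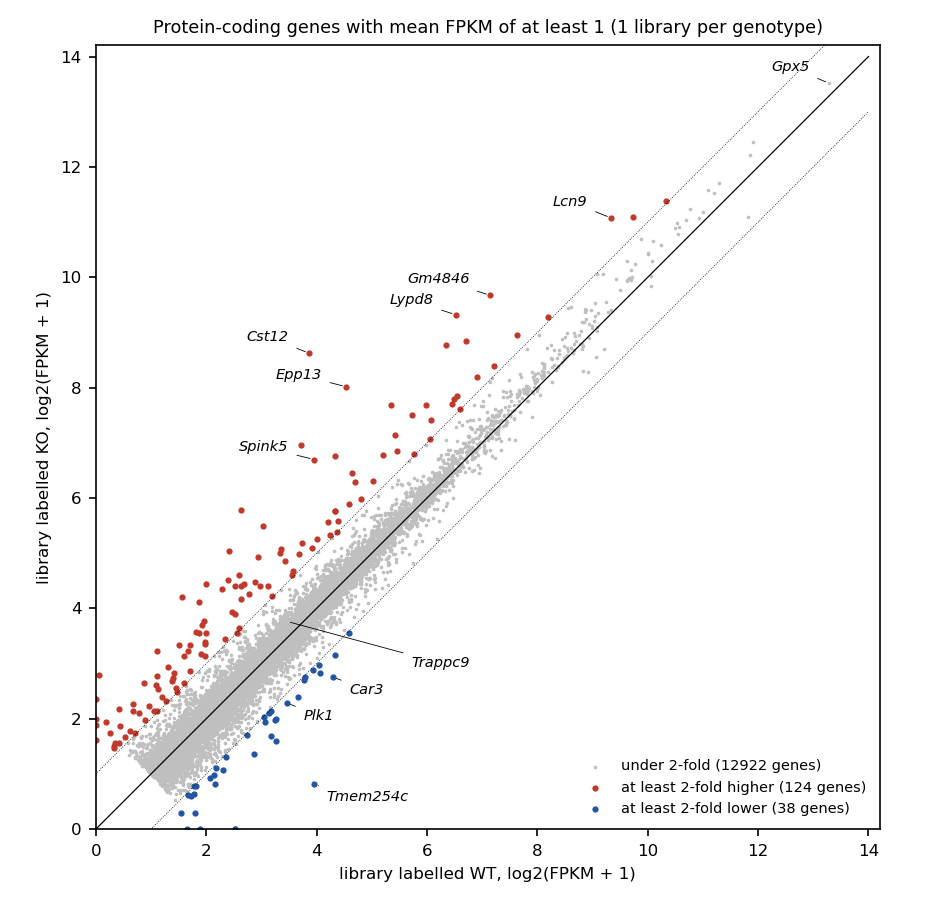
Level of each protein-coding gene with a mean of at least 1 FPKM in the library labelled WT (x axis) and the library labelled KO (y axis), both as log2(FPKM + 1), 1 point per gene. The solid line marks equal levels and the dotted lines a 2-fold difference; 124 genes lie on or above the upper dotted line and 38 on or below the lower one, and Trappc9 lies close to the line of equal levels.

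Among the 12 genes with the highest ratios were the cystatin gene Cst12, the beta-defensin genes Defb22 and Defb45, and Prm2, Smcp and Odf1, genes of maturing sperm. Another cystatin gene, Cst9, was among the 12 lowest. Cst12, a cystatin, stood at 13.6 FPKM in the library labelled WT and 393 FPKM in the library labelled KO, a log2 ratio of 4.76 with a ratio of 29.0 (counting interval 24.2 to 34.9). Epp13 (22.3 and 258 FPKM) followed with a log2 ratio of 3.47, then the beta-defensin Defb22 (12.1 and 123 FPKM) with 3.24. Prm2, a protamine that packs DNA in spermatids, was at 5.21 and 54.1 FPKM (3.15). Lypd8 (91.2 and 638 FPKM), the protease inhibitor Spink5 (14.5 and 103 FPKM), Nxph4 (1.94 and 17.4 FPKM), the sperm mitochondrial protein gene Smcp (4.33 and 31.9 FPKM), Gm4846 (141 and 815 FPKM), Defb45 (7.17 and 44.2 FPKM), the sperm tail gene Odf1 (3.00 and 20.8 FPKM) and 9230113P08Rik (19.1 and 107 FPKM) completed the 12 genes, with log2 ratios of 2.79 down to 2.43.

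Lower genes were fewer, and apart from Tmem254c the 12 lowest had ratios smaller in size than the 12 highest. Tmem254c was at 14.5 and 0.75 FPKM (326 and 17 fragments), a log2 ratio of −3.15; its near-identical copies Tmem254a and Tmem254b share reads with it, but the sum over the 3 copies was 14.6 and 0.75 FPKM. CR974586.3 (8.60 and 2.02 FPKM) rested on 38 and 9 fragments. Car3, a carbonic anhydrase abundant in adipocytes, was at 18.5 and 5.76 FPKM (−1.53), and the hormone genes Iapp (7.97 and 2.23 FPKM) and Sct (11.6 and 4.23 FPKM) had ratios of −1.48 and −1.27. Also among the 12 were Pdcl2 (8.64 and 2.99 FPKM), Cst9 (8.53 and 2.95 FPKM), the serotonin receptor gene Htr5b (15.6 and 6.11 FPKM), Ppp1r8 (19.2 and 7.87 FPKM), the mitotic kinase gene Plk1 (9.98 and 3.88 FPKM), Cmtm2b (7.38 and 2.86 FPKM) and Lgals7 (12.6 and 5.51 FPKM).

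**Figure D2:**
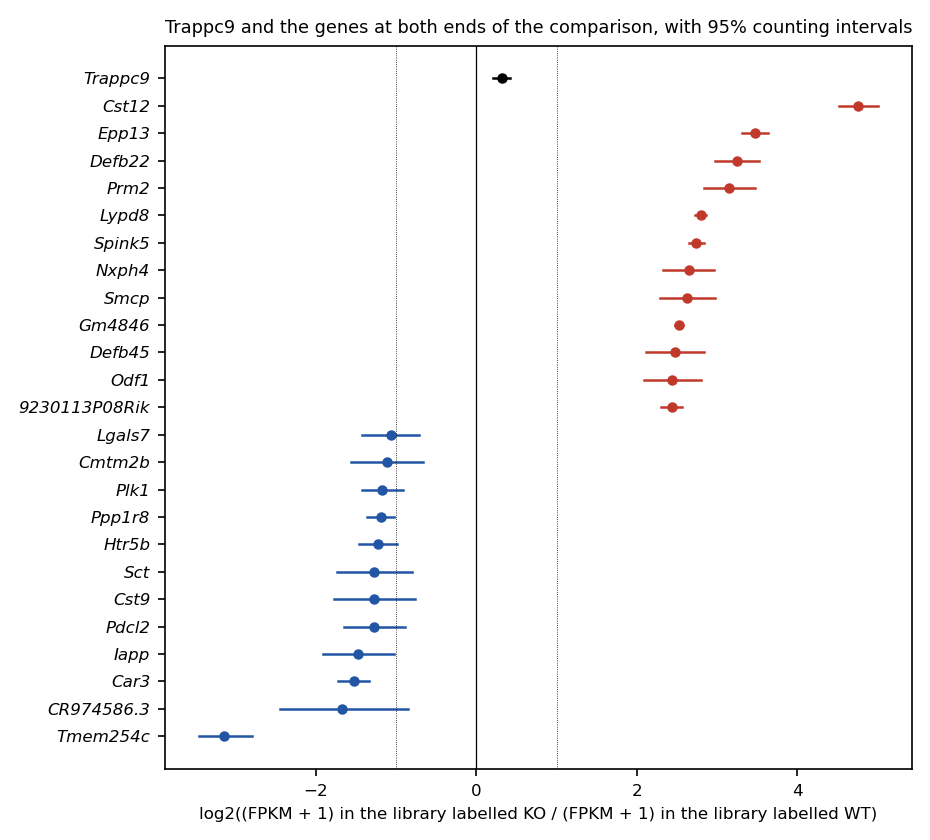
Log2 ratio of FPKM + 1, library labelled KO over library labelled WT (x axis), for Trappc9 and for the 12 genes at either end of the comparison (y axis), as points with 95% counting intervals as bars; dotted lines mark a 2-fold difference. Trappc9 lies at 0.32, the genes at the upper end between 2.43 and 4.76, and those at the lower end between −1.07 and −3.15.

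Of the 44 gene lists that could be ranked, 7 stood above their matched random lists, 11 below and 26 within. A list's place was set against random lists under the same scaling, whereas positive medians smaller than the TPM shift can turn negative under it. Proliferation and extracellular matrix showed the largest differences. All 30 cell cycle genes were lower beyond counting error (median −0.60), with Mki67 at 12.5 and 6.57 FPKM, Ccna2 at 7.94 and 3.65 FPKM and the spindle gene Tpx2 at 8.03 and 3.39 FPKM. Of 26 collagen and matrix genes, 25 were lower (median −0.46), including elastin, Eln, at 71.4 and 37.4 FPKM and Col3a1 at 481 and 312 FPKM; the exception, Ctgf, had a log2 ratio of 0.55 and was named after its value was seen. No member of the matrix list and 2 of the cell cycle list, Plk1 and Tpx2, reached 2-fold. In the same libraries, levels of several epididymal and spermatid genes were higher in the library labelled KO, as given above for Cst12, Defb22 and Prm2, while meiotic spermatocyte genes, a list written after the values were seen, were lower (median −0.54, with 10 of 15 lower and 2 higher beyond counting error).

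Lists of adipose precursor cells stood below as well, by smaller amounts. Early adipose progenitor markers had a median of −0.12, with 8 of 14 lower beyond counting error, among them Cd34 (52.6 and 27.4 FPKM) and Pi16 (18.2 and 12.2 FPKM), whereas Dpp4 (18.9 and 21.5 FPKM) and Ly6a (67.5 and 78.9 FPKM) were higher. Committed preadipocyte markers had a median of −0.17, with Dlk1 at 8.80 and 4.35 FPKM and Lpl at 9.96 and 6.37 FPKM; Pdgfra was at 34.2 and 30.7 FPKM, Fabp4 at 25.1 and 27.0 FPKM and Apod, at 9.75 and 27.9 FPKM, went the other way. Several of these markers, such as Fn1 and Col15a1, also belong to the matrix list. Insulin and IGF signalling genes (median −0.17) included Grb10 at 10.4 and 7.76 FPKM and Irs1 at 2.09 and 1.60 FPKM. Wnt pathway genes (median −0.12) included Wnt10b at 3.45 and 1.60 FPKM and Sfrp2 at 12.7 and 8.57 FPKM, while Wnt11 was at 1.37 and 2.35 FPKM. Mesothelial markers had a median of −0.22, with Upk3b at 23.0 and 10.8 FPKM, Msln at 14.8 and 10.2 FPKM and Upk1b, at 14.8 and 25.3 FPKM, opposite. Cholesterol synthesis (median −0.05), ER stress (−0.05) and immediate early genes (−0.01) stood below with medians close to 0, and neutrophil markers (−0.39) rested on 5 measured members, of which Ltf (4.26 and 21.8 FPKM) and Mmp9 (3.31 and 2.29 FPKM) went in opposite directions. None of these last 4 lists stayed below in every setting.

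Of the 7 lists above, only the endothelial one kept its place in every setting. Of 25 lysosome and autophagy genes, 18 were higher beyond counting error (median 0.22), with Npc2, a cholesterol carrier of the lysosome, at 114 and 205 FPKM and Lamp1 at 209 and 290 FPKM. Monocyte and dendritic cell markers (median 0.37, but −0.0027 and within without the filter on FPKM) were led by the MHC class II genes Cd74 (113 and 169 FPKM) and H2-Eb1 (42.3 and 62.5 FPKM). B and plasma cell markers (median 0.39, but −0.04 after rescaling to TPM) were led by the antibody genes Igkc (13.1 and 43.6 FPKM) and Ighm (17.4 and 33.5 FPKM), which can share reads with other antibody segments, and Cd79a was at 0.78 and 0.48 FPKM. Endothelial markers (median 0.18) included Pecam1 at 7.45 and 9.50 FPKM and Sox17 at 1.83 and 3.84 FPKM. Markers of type 2 innate lymphoid cells, eosinophils and mast cells had a median of 0.22, with the mast cell tryptase gene Tpsb2 at 1.83 and 3.62 FPKM. Erythroid genes had a median of 0.27, with Hbb-bt, which resembles Hbb-bs, at 33.6 and 55.1 FPKM. Mitochondrially encoded genes had a median of 0.39, with mt-Co1 at 3853 and 5590 FPKM. With list means in place of medians the lysosome, monocyte, erythroid and mitochondrial lists came within, and without their farthest member so did the erythroid, type 2 lymphoid and B cell lists.

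**Figure D3:**
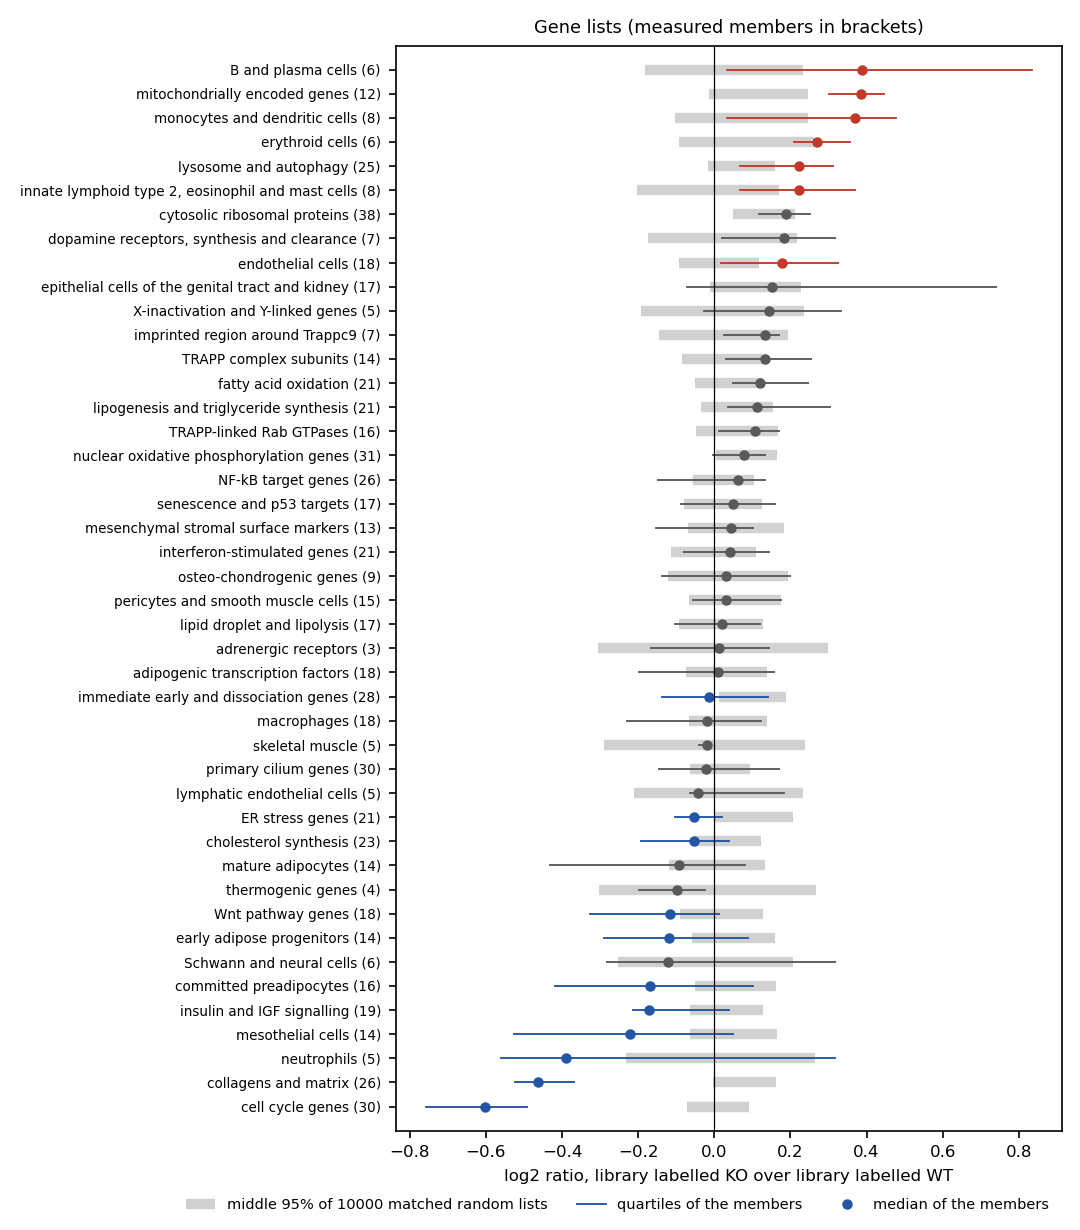
Median log2 ratio, library labelled KO over library labelled WT (x axis), of each of the 44 ranked gene lists (y axis, measured members in brackets). Points are medians and thin bars the quartiles of the members, in red for lists above, blue for lists below and dark grey for lists within their matched random lists, whose middle 95% is the broad grey bar; cell cycle genes (−0.60) and matrix genes (−0.46) lie farthest from it.

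The series title concerns dopamine transmission and metabolic disturbance, and most lists close to these themes stood within their matched random lists, except insulin and IGF signalling and cholesterol synthesis, which stood below as given above. Of the dopamine receptors, Drd1, Drd2 and Drd3 had 9 or fewer fragments in either library and Drd5 had 0 in both, which allows up to 0.067 FPKM in either, so differences in them were not detectable at this depth. Drd4 was at 0.71 and 1.12 FPKM. Genes of dopamine receptors, synthesis and clearance had a median of 0.18, within the random lists. Only 7 of its 16 members were measured and no dopamine receptor was among them, so the list does not describe the receptors. Ppp1r1b, a target of dopamine signalling, was at 3.81 and 8.21 FPKM and Maob at 20.5 and 25.4 FPKM. Adrenergic receptors (median 0.01, 3 of 9 measured) were within. Adrb3, at 0.40 and 0.31 FPKM, was too low to count among the measured members. Adipogenic transcription factors (median 0.01) were within, with Pparg at 1.75 and 1.33 FPKM and Cebpa at 10.2 and 13.8 FPKM. Lipogenesis (0.11), lipid droplet and lipolysis (0.02), fatty acid oxidation (0.12) and thermogenic genes (−0.10, 4 of 18 measured, without Ucp1) were all within. Fatty acid oxidation, at percentile 96.5, did not stay within in every setting. Single members nonetheless differed beyond counting error in both directions: the triglyceride synthesis gene Lpin1 (3.84 and 6.25 FPKM), Plin4 (3.42 and 5.95 FPKM) and Cpt1a (39.9 and 55.2 FPKM) were among those higher, and Plin1 (1.87 and 1.11 FPKM), Etfb (6.79 and 4.56 FPKM) and Ebf1 (1.66 and 1.08 FPKM) among those lower. Ucp1 had 2 and 6 fragments.

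NF-kB target genes, of interest because TRAPPC9 protein is known to bind NF-kB kinases, had a median of 0.06, within the random lists. Beyond counting error, 7 of 26 members were higher and 7 lower, against 3220 and 2297 of all 13084 genes. The chemokine genes Cxcl1 (36.5 and 22.1 FPKM), Ccl2 (20.8 and 13.9 FPKM) and Ccl7 (18.8 and 12.8 FPKM) were lower, Nfkbia was at 86.3 and 93.1 FPKM, Tnf at 6.12 and 5.46 FPKM and Il6 at 9.54 and 8.06 FPKM. Interferon-stimulated genes (0.04), senescence and p53 targets (0.05), cytosolic ribosomal proteins (0.19), nuclear oxidative phosphorylation genes (0.08), primary cilium genes (−0.02) and osteo-chondrogenic genes (0.03) were within. Among these, Lmnb1 was at 23.3 and 15.2 FPKM, Gli1 at 5.88 and 4.07 FPKM and Alpl at 24.9 and 40.0 FPKM.

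Marker levels described what the libraries held. Adipocyte markers were low in both: Adipoq was at 2.30 and 0.51 FPKM (45 and 10 fragments), Lep at 0.063 and 0.083 FPKM, and the mature adipocyte list, 0.0573% and 0.0491% of all fragments, had a median of −0.09, within the random lists. Also within were mesenchymal stromal surface markers (0.04), macrophages (−0.02, Adgre1 at 6.41 and 5.40 FPKM), lymphatic endothelium (−0.04), pericytes and smooth muscle (0.03), skeletal muscle (−0.02) and Schwann and neural cells (−0.12). T and NK cell and pancreatic acinar markers had 1 measured member each and were not ranked: Klrb1c stood at 28.2 and 50.7 FPKM and Cela1 at 2.45 and 2.70 FPKM, while Cd3e was at 0.17 and 0.22 FPKM and Ptprc, the pan-leukocyte gene, at 1.12 and 1.06 FPKM. Ddx3y, on the Y chromosome, was at 14.6 and 19.7 FPKM, and Xist, transcribed from the inactive X of females, at 2.01 and 2.79 FPKM. The sex-linked list had a median of 0.14, within. As it holds Xist and Y-linked genes together, this median cannot show a difference in the share of the sexes.

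Epithelial genes of the male genital tract were among the most abundant transcripts in both libraries. In the list of genital tract and kidney epithelium (17 measured, median 0.15 and −0.05 after rescaling to TPM, within), Lcn8 stood at 3719 and 4750 FPKM and Lcn5 at 1284 and 2667 FPKM, against 226 and 216 FPKM for the general epithelial gene Epcam. Of its members, 4 were at least 2-fold higher in the library labelled KO: Lcn9 (646 and 2154 FPKM), Rnase9 (197 and 494 FPKM), Cst8 (292 and 617 FPKM) and Lcn5. Gpx5, an epididymal glutathione peroxidase named after its value was seen, was the most abundant protein-coding gene of each library, at 10039 and 11686 FPKM. In a choice made after the data were seen, the listed epididymal and germ cell genes and all genes with Defb, Spink, Lcn, Cst or Rnase symbols were left out. This left 91 genes at least 2-fold higher and 34 lower. Reproductive genes outside these lists, such as the germ line gene Mael, were still counted.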

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

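The tests of gene length and the 3 tests on Trappc9 were chosen only after the results they measure were seen; those on further epididymal, epithelial, germ cell, short and fibroblast genes were written before their values were looked at.

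A set of 33 genes of the epididymis, the duct in which sperm mature, 8 of which are also in the fixed genital tract list, held 4.52% of the fragments in the library labelled WT and 5.58% in the library labelled KO, flagged as a signal outside the adipose measurement; it was assembled after the values were seen. A candidate explanation is that cells of the epididymis, which lies against the gonadal fat pad, were in the dissected pads. Of 16 further epididymal genes that no other list holds, 15 were at 10 FPKM or more in both libraries, as this explanation needs. Inflation of short genes by the FPKM unit is argued against by the lowest share of fragments, 4.52%, which does not depend on length, and a sample of another tissue under these labels stays open, as no library here is known to be free of epididymis. Both genotypes carry the signal, so no biological explanation by genotype was tested for its presence. Whether the 70-µm strainer and pelleting described for the preparation remove epithelial cells was not tested.

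Trappc9 was not lower in the library labelled KO, with 1432 fragments there. Scaling is argued against, since the lowest log2 ratio under any scaling tried was 0.14. An exchange of the labels together with an allele that removes most of the transcript is argued against too, since the library labelled WT would then hold far less of it, and the upper bound of the KO over WT ratio was 1.37. What stays open is an allele that leaves the transcript in place, for example a small deletion or an inserted cassette downstream of most exons, and it cannot be told apart from a library of unaltered genotype because the 1432 fragments are a sum over the whole gene. Exchanged labels with such an allele stay open for the same reason.

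In the library labelled KO some epididymal secretory genes were higher and matrix genes lower, while spermatid genes, flagged as a second signal outside adipose tissue, held 0.0204% of the fragments in the library labelled WT and 0.0254% in the library labelled KO. The 33 epididymal secretory genes had a median log2 ratio of 1.301. The upper quartile was 0.196 for further epithelial genes and 0.32 for other genes of at most 1000 bases. As the 33 genes were picked from those already seen to be high in these libraries, the size of their median may owe to that choice. These comparisons therefore cannot decide on more epithelium or on a bias towards short genes. The 16 further epididymal genes, chosen without looking at their values, had a median of 0.15, against 0.11 for the further epithelial genes. Fewer fibroblasts as the whole cause of the lower matrix genes is argued against by the lower quartile of non-matrix fibroblast genes, −0.32, above the matrix median of −0.46. This holds only if other cells add little to these fibroblast genes, which was not tested. The quartiles of the further matrix genes, −0.56 and −0.27, enclose the −0.32. The median of the non-matrix fibroblast genes, −0.18, was below the matched random lists and leaves room for a part. More mature reproductive tissue in the library labelled KO stays possible but is not decided. The median of spermatid genes exceeded that of meiotic spermatocyte genes by 1.41, as a later stage of the first wave of sperm formation would give. Both lists were written after values were seen, with Prm2, Smcp and Odf1 among the 12 highest genes, so other genes of the same stages could repeat that split. The 16 further epididymal genes stood within their matched random lists. An age difference within the 3 to 4 weeks, a difference in dissection and an effect of the genotype all stay open and untested, since the design has 1 library per genotype.

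Genes of other biotypes are outside the main count. Among 2363 of them with a mean of at least 1 FPKM, 153 were at least 2-fold higher and 118 lower in the library labelled KO, of which 77 and 54 exceeded counting error; 38 and 44 were microRNA genes, whose short annotated length turns few fragments into large FPKM values.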

How the results depend on the processing

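No paired analysis was possible because each genotype has 1 library, and no library could be left out. The directions of the cell cycle, matrix, insulin and IGF, Wnt, early progenitor, committed preadipocyte, mesothelial and endothelial lists, and their places outside the matched random lists, held in every setting that ranked lists; these are 8 of the 18 lists outside. Over 13 such settings, 538 of 564 list results kept their place above, below or within, 15 moved inside, 7 moved outside and 4, counted only for lists outside, changed sign: monocytes and dendritic cells without a filter (−0.0027), B and plasma cells after rescaling to TPM (−0.037), and, with means in place of medians, immediate early genes (0.0012) and neutrophils (0.16). For the 26 lists within, the sign of the median was not counted as a place, and it changed in 59 of 332 results, over 21 of these lists. The lists within that moved outside in at least 1 setting were fatty acid oxidation, cytosolic ribosomal proteins, mature adipocytes, lymphatic endothelium, genital tract and kidney epithelium, and Schwann and neural cells. With list means 4 lists stood above. The counts of higher and lower genes were 208 and 130 with a pseudocount of 0.1 FPKM and 66 and 2 with 5 FPKM, by construction the weight given to low genes; 365 and 276 at 1.5-fold; 23 and 3 at 4-fold; and 277 and 156 over all biotypes. With a mean of at least 5 FPKM, 19 genes were lower. TPM gave 277 lower genes and a Trappc9 log2 ratio of 0.14, and rescaling without the most abundant genes gave 253 higher and 297 lower; both also raise all values, so that a pseudocount of 1 weighs less. For the other changes of sign or count the cause was not tested. Each library's own total, chosen after the data were seen, gave 106 and 49 and 0.23 for Trappc9. Gene results were compared for 276 genes, Trappc9 apart, that the naming rules picked or that were added later, not all of them named in the text. Of their 1932 results, 1478 stayed within their counting interval, 454 moved beyond it and 0 of the called ones changed sign. Depth limits statements on receptors and immune markers with few fragments, where the counting intervals are wide.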

Other observations

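The lists in this part, and the genes outside the fixed rule, were chosen after values were seen, as were the tests on them except those named above.

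Genes of the male germ line and epididymis split into groups. Of 15 measured meiotic spermatocyte genes, 10 were lower in the library labelled KO beyond counting error and 2 higher, Rec8 and Spo11 (median −0.54, below the matched random lists), with Ddx4 at 3.77 and 1.65 FPKM, Ldhc at 38.3 and 20.5 FPKM and Mael at 14.3 and 6.37 FPKM, the last 2 from outside the list. Of 16 measured spermatid genes, 11 were higher beyond counting error and 3 lower, Hils1, Akap3 and Spaca1 (median 0.88, above), with Akap4 at 1.66 and 6.12 FPKM, Tnp2 at 10.8 and 24.7 FPKM and Gapdhs at 5.04 and 10.4 FPKM. Sertoli and Leydig cell genes had 4 measured members and a median of −0.08, within, with Insl3, a Leydig cell hormone, at 1.81 and 1.68 FPKM and the steroid synthesis gene Cyp17a1, the 1 member higher beyond counting error, at 5.54 and 10.1 FPKM. Of the 33 epididymal secretory genes, 31 were higher beyond counting error, 19 of them at least 2-fold, such as Crisp4 (19.1 and 53.5 FPKM), and others by less, such as Gpx5 (10039 and 11686 FPKM) and Cst11 (2052 and 2331 FPKM). The 2 lower were Defb47 (3585 and 2174 FPKM) and Teddm1a. The 16 further epididymal genes, chosen without looking at their values, had 8 higher and 2 lower, Lcn6 (452 and 316 FPKM) and Etv4, with Ros1 at 39.7 and 40.2 FPKM and a median of 0.15, within the random lists, so the higher median of the 33 secretory genes (1.301), which were picked from these libraries, does not extend to these 16. Of 33 measured beta-defensin genes, 10 were at least 2-fold higher and 0 lower, with a median of 0.53 and a lowest median of 0.34 over the scalings tried. Other secretory families had fewer measured genes. Of 9 Kazal protease inhibitor genes 4 were at least 2-fold higher (Spink2, Spink5, Spink11 and Spink13) and 2 lower (Spink4 and Spink6), with a median of 0.72, and of 6 cystatin genes 2 were higher (Cst8 and Cst12) and 1 lower (Cst9), with a median of 0.14 that was −0.06 after rescaling to TPM. Of 7 lipocalin genes (median 0.55) 2 were higher (Lcn5 and Lcn9), of 5 ribonuclease-family genes (median 0.21) 2 (Rnase9 and Rnase13), and 0 of either lower.

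The lower matrix level was also present in a second list: 22 further matrix genes, of which 20 were measured, had a median of −0.41, below the random lists, with 17 lower beyond counting error. Further epithelial genes had a median of 0.11, within.

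The long noncoding RNA gene Gm42031 (chromosome 8, 85125872 to 85132289, mm10) was at 57.8 FPKM in the library labelled WT, from 1544 fragments, and at 0.41 FPKM in the library labelled KO, from 11 fragments. Ptgds (51.7 and 182 FPKM) and Ido1 (43.1 and 114 FPKM) were higher in the library labelled KO. Gapdh was listed at 2.19 and 8.32 FPKM, a low level for a gene that most cells use at a high level, and its reads are shared with many pseudogenes, so its value is uncertain.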
